A study of Mus musculus with 6 samples.

How the data were processed

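Renal cortex RNA was sequenced from 3 mice on the diet alone and 3 mice on the diet with tofogliflozin, all for 8 weeks. Per the labels' protocols, total RNA was extracted with a column kit and libraries were made with a strand-specific mRNA kit. The authors deposited 1 table per library, with a gene symbol and an FPKM value for each of 24346 genes. Per the submitters' processing notes, the tools named are TopHat2 2.1.1, Bowtie2 2.2.8, SAMtools 0.1.18 and Cuffdiff 2.2.1, and the genome build is mm10; their order and role, the gene annotation, the use of strand in counting and the normalization between libraries are not given in the sources used here. The upper quartile of the deposited FPKM over all genes lay between 10.5 and 10.6 in the 6 files, while the totals ran from 565754 to 633338, so a scaling between libraries may already be in the values. Kap, a kidney androgen-regulated gene, alone made up 7.98% to 11.1% of the total FPKM of a library.

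Groups and replicate numbers were taken from the labels, which give 3 mice per group. No 2 libraries held identical values beyond single genes. The files hold no counts, so depth was read from the values. Where fragments are counted whole, a gene's values are whole multiples of what 1 fragment is worth. Over genes below 0.3 FPKM in every library, 76.3% of 5460 values were within 1% of a whole multiple of the gene's lowest value. The steps gave the relative depth, and the lengths of 353 single-transcript genes an approximate total of 7830000 fragments for diet replicate 1 (quartiles 6840000 and 8050000) and up to 10100000 for tofogliflozin replicate 1. These totals are estimates, and no count test was run. Rpl26, a ribosomal protein gene, is listed at 0 in 3 libraries, so a value of 0 may be a failed estimate. Genes with such a value are given library by library.

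From the FPKM values the following was computed. Genes with at least 1 FPKM in at least 3 of the 6 libraries were kept (12248) and put on the log2(FPKM + 1) scale, on which a fold change understates that of low genes. The groups were compared with limma 3.58.1 in R 4.3.3 (moderated test with a mean-variance trend, two-sided), with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. Gene lists, 41 in all with 862 distinct genes, were tested with camera at a preset correlation of 0.01 (two-sided, adjusted over the 37 lists with at least 5 tested members), with camera at an estimated correlation and with fry beside it. Single genes of a list were also adjusted over the list alone, which makes no allowance for the number of lists. Standard errors and 95% intervals are limma's. The pseudocount is 1. The groups, tests, filter, lists, rule for named genes and alternative settings were fixed before the data were examined.

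Genes are named by this rule: up to 12 genes in each direction with the largest log2 change among those past the threshold with all libraries apart, predicted genes being counted only; where fewer pass, up to 5 genes of smallest p that did not pass; 25 fixed genes of glucose transport, lipid handling, inflammation, fibrosis and injury; and up to 4 members of smallest p from each list. Some genes that the rule selects are not reported here, and counts and list tests include them. Any gene named outside this rule is said to be so. Coordinates are from the GRCm38 annotation, the build of the files, in which 193 of 195 genes named by the rule have a position, 2 of them by an older symbol.

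The alternatives were another pseudocount (0.1), no filter and a stricter filter (5 FPKM), upper-quartile scaling, quantile normalization, leaving out each library, the replicate number as a block, array weights, no trend, a robust trend and a threshold of 0.1. Leave-out counts over single lists were added after the data were seen. The fit was tested on simulated data for this comparison, with 200 of 12248 genes changed and the oxidative phosphorylation list moved by 0.3 (log2). It recovered 31.8% of genes changed by 0.5 on the log2 scale, 92.4% of those changed by 1 and 100% of those changed by 2. Among 157 genes called, 9 were unchanged genes outside the moved list. The moved list was called (camera adjusted p = 1.69e-26) and 0 other lists were. When nothing was changed, 2 genes and 0 lists were called. Noise was drawn independently for each simulated gene, so these list results do not test lists whose genes vary together. The 200 changed genes were drawn from those clearly above the filter level, so the recovered shares do not cover genes near 1 FPKM. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.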

Results

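RNA-seq of the renal cortex was carried out on 6 C57BL/6 mice, all fed for 8 weeks a diet rich in fat, cholesterol and bile salt that is used to induce steatohepatitis. In 3 of the mice the diet contained tofogliflozin, an inhibitor of SGLT2, the glucose transporter of the early proximal tubule that is encoded by Slc5a2. The other 3 received the diet alone and served as the control. Mice on a standard diet were not analysed here. The deposited values are FPKM for 24346 genes in each library, with no counts. The spacing of the lowest values placed the depth at about 7830000 to 10100000 fragments per library, and tofogliflozin replicate 1 was the deepest, with 1.29 times the fragments per FPKM of diet replicate 1. A transcript of 2 kb at 1 FPKM then rests on about 15.7 to 20.3 fragments, so genes near 1 FPKM carry a large counting error. The correlation of log2 values between libraries lay between 0.980 and 0.990 for every pair, within and between groups.

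The first question was which genes of the renal cortex differed between mice given tofogliflozin and mice given the diet alone. As groups, PPARα targets and gluconeogenesis genes were higher and macrophage markers lower at a preset correlation, and no group was called with an estimated correlation. The macrophage call also ended without diet replicate 2 (camera adjusted p = 0.548). Of 12248 genes tested, 24 rose and 7 fell with the drug (limma, Benjamini-Hochberg adjusted p under 0.05). Bcat1, which encodes the cytosolic branched-chain amino acid aminotransferase, had the smallest p and rose from 3.58 ± 0.0914 to 16.6 ± 2.08 FPKM (mean ± SD, n = 3 per group; limma adjusted p = 0.000640). Its log2 change was 1.93 ± 0.10 (SE). Scgb1c1, a member of the secretoglobin family, was listed at 0, 0 and 1.37 FPKM in the diet libraries and at 17.7, 21.6 and 23.0 FPKM in the tofogliflozin libraries (limma adjusted p = 0.00755). Chst11, a chondroitin sulfotransferase, fell from 20.3 ± 1.43 to 11.7 ± 1.55 FPKM (limma adjusted p = 0.0435).

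Among the other genes that rose, Hyal1, a lysosomal hyaluronidase, went from 5.04 ± 0.803 to 17.4 ± 2.62 FPKM and Elovl2, an elongase of very long polyunsaturated fatty acids, from 4.47 ± 0.579 to 12.5 ± 1.63 FPKM. Their log2 changes were 1.61 ± 0.13 and 1.30 ± 0.12 (SE). Tsc22d3, which encodes the glucocorticoid-induced leucine zipper, rose from 27.2 ± 4.72 to 66.2 ± 6.85 FPKM, and Serpina1a, an alpha-1-antitrypsin gene, from 17.7 ± 2.61 to 44.2 ± 10.4 FPKM. Bhmt, which remethylates homocysteine with betaine, rose from 1.71 ± 0.320 to 8.07 ± 2.69 FPKM. Sec14l3, of the SEC14-like lipid-binding family, rose from 2.0 ± 0.685 to 11.4 ± 3.72 FPKM, and Stk32c, a serine/threonine kinase gene, from 1.70 ± 0.122 to 4.67 ± 0.369 FPKM. Klk1b21 was at 0.167, 0.167 and 0.307 FPKM in the diet libraries and at 2.84, 2.47 and 4.45 FPKM with tofogliflozin, and passed the filter only through the latter. On the scale used, which understates the change of such low genes, the log2 change was 1.78 for Klk1b21 and 1.24 for Klk1b24, which are glandular kallikrein genes. It was 1.75 for Ugt1a10, a glucuronosyltransferase. The close relatives of Klk1b21, Klk1b24 and Ugt1a10 in the same gene clusters, and those of Serpina1a, can share reads with them. Hyal1 overlaps Hyal3 and Naa80 on the same strand, so the values of all these genes are uncertain. The limma adjusted p of the genes in this paragraph ran from 0.00769 for Hyal1 to 0.0437 for Serpina1a.

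The genes that fell also included Smcp, a sperm mitochondrial protein gene, from 5.70 ± 1.32 to 1.03 ± 0.440 FPKM, and Arhgef19, a guanine nucleotide exchange factor gene, from 10.6 ± 1.71 to 4.23 ± 0.705 FPKM. Adam11, a member of the ADAM family, fell from 3.58 ± 0.293 to 1.37 ± 0.332 FPKM. D14Ertd670e was listed at 3.55, 2.90 and 2.37 FPKM in the diet libraries and at 0.749, 0 and 0.287 FPKM with tofogliflozin, and 1 predicted gene also fell. Limma adjusted p of the genes named so far in this paragraph ran from 0.0188 for Smcp to 0.0406 for Adam11. The next 5 genes by p in this direction did not pass, with limma adjusted p from 0.0532 for Pzp to 0.0638 for Qprt. Pzp, an alpha-2-macroglobulin relative, was at 72.4 ± 20.7 and 22.2 ± 7.0 FPKM (diet and tofogliflozin) and Stra6l at 5.85 ± 0.391 and 2.81 ± 0.588 FPKM. St8sia1 was at 24.7 ± 0.631 and 17.1 ± 1.34 FPKM, Bcl3 at 5.11 ± 0.0323 and 2.93 ± 0.336 FPKM, and Qprt at 60.2 ± 2.67 and 43.0 ± 3.12 FPKM.

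In the mm10 (GRCm38) annotation, Bcat1 lies on the minus strand of chromosome 6 from 144993835 to 145076184, and Scgb1c1 on the plus strand of chromosome 7 from 140845547 to 140846769. Hyal1 spans 107576927 to 107581710 on chromosome 9, and Elovl2 spans 41182381 to 41220405 on chromosome 13. Tsc22d3 lies on chromosome X from 140539528 to 140600659, and Slc5a2, the gene of the drug's target, on chromosome 7 from 128265657 to 128272430. Each value is for the whole gene, so it does not tell exons or transcripts apart.

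All 31 genes had every tofogliflozin library on one side of every diet library, as did 2265 of the tested genes (18.5%), where chance gives 10% for 3 against 3. Before adjustment 1604 genes had p under 0.05, 821 higher and 783 lower, where 612 are expected by chance. Bcat1 passed the threshold in 15 of 15 other settings tried, Hyal1 in 14, Elovl2 in 13 and Scgb1c1 in 12. The count of changed genes was 9 without diet replicate 1, 66 without diet replicate 2, 57 without diet replicate 3, 4 without tofogliflozin replicate 1, 18 without tofogliflozin replicate 2 and 2 without tofogliflozin replicate 3. It was 1 when no filter was set on low values and 17726 genes were tested.

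**Figure D1:**
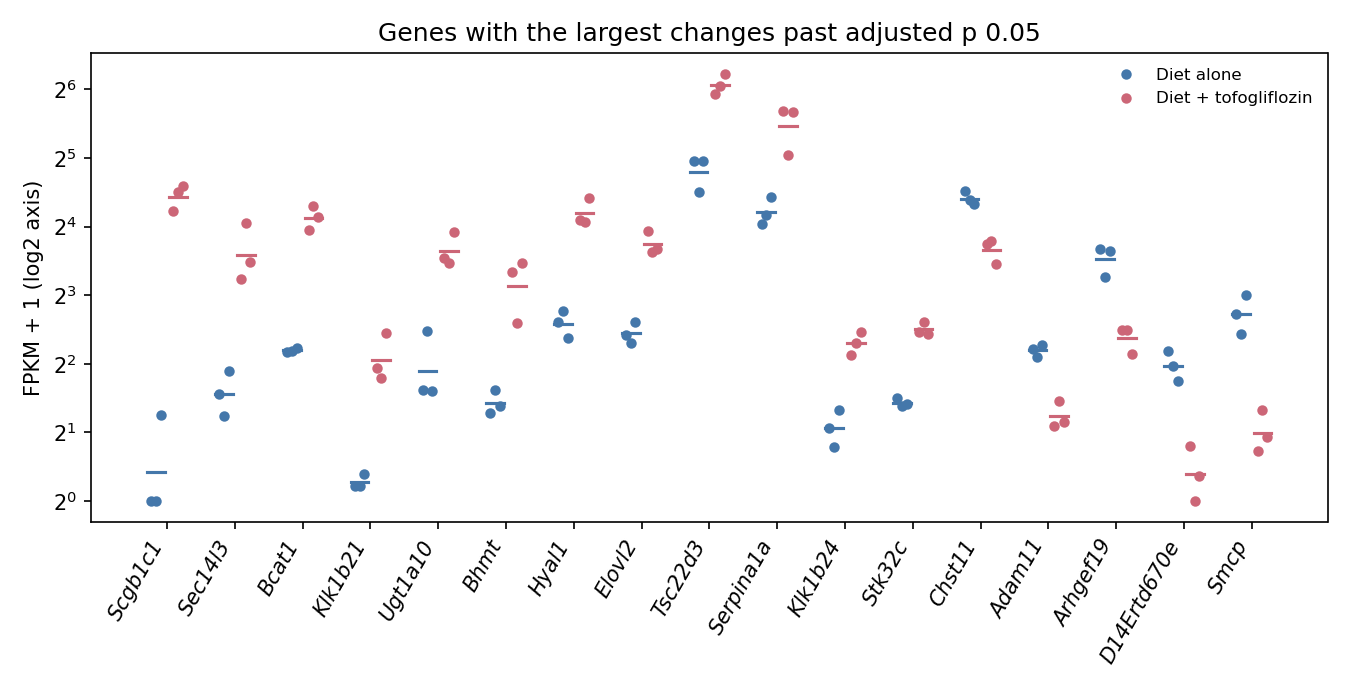
FPKM + 1 on a log2 axis of the genes named in the text that passed the threshold with the largest changes, 1 point per library, with a line at the mean of the log2 values of the 3 libraries of each group. Blue is the diet alone and red the diet with tofogliflozin, and the groups do not overlap for any gene shown; for Bcat1 the diet libraries sit at a mean of 3.58 FPKM and the tofogliflozin libraries at 16.6 FPKM.

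The second question, named in the title of the series, concerned lipid handling and PPARα, the nuclear receptor that induces genes of fatty acid oxidation. Of 50 PPARα target genes measured, 42 had a log2 change above 0, with a median of 0.19. Of the 50, 17 rose and 1 fell when adjusted over the list alone, and none passed over all genes tested (20 higher and 2 lower at an unadjusted limma p under 0.05). In this and the later paragraphs on lists, a named gene said to rise or fall passed over all genes only where that is stated. Angptl4, a secreted inhibitor of lipoprotein lipase, rose from 42.4 ± 8.09 to 107 ± 33.9 FPKM, and Acaa1b, a peroxisomal thiolase, from 109 ± 6.50 to 175 ± 23.7 FPKM, both adjusted over the list alone. Cyp4a14, a fatty acid hydroxylase gene with close relatives that can share its reads, was at 13.5, 13.2 and 15.6 FPKM in the diet libraries and at 59.3, 27.9 and 125 FPKM with tofogliflozin.

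Ppara itself was at 32.8 ± 4.41 and 42.0 ± 7.07 FPKM, a log2 change of 0.34 (95% interval 0.03 to 0.66; limma adjusted p = 0.339), and did not pass. As a group the PPARα targets were higher relative to other genes at camera's preset correlation (adjusted p = 2.65e-09), a call that was lost at an adjusted p of 0.659 with an estimated correlation. In a check chosen after the data were seen and used below for all lists, the genes that passed over the list alone were counted with each library left out. The PPARα targets that passed numbered 8 without diet replicate 1 and 7 without tofogliflozin replicate 3, all higher. Without diet replicate 2 they numbered 8, of which 6 were higher and 2 lower. The mean deviation of the list was largest in tofogliflozin replicate 3, at 0.39 on the log2 scale, against 0.02 and 0.12 in the other tofogliflozin libraries and -0.11, -0.30 and -0.12 in the diet libraries.

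**Figure D2:**
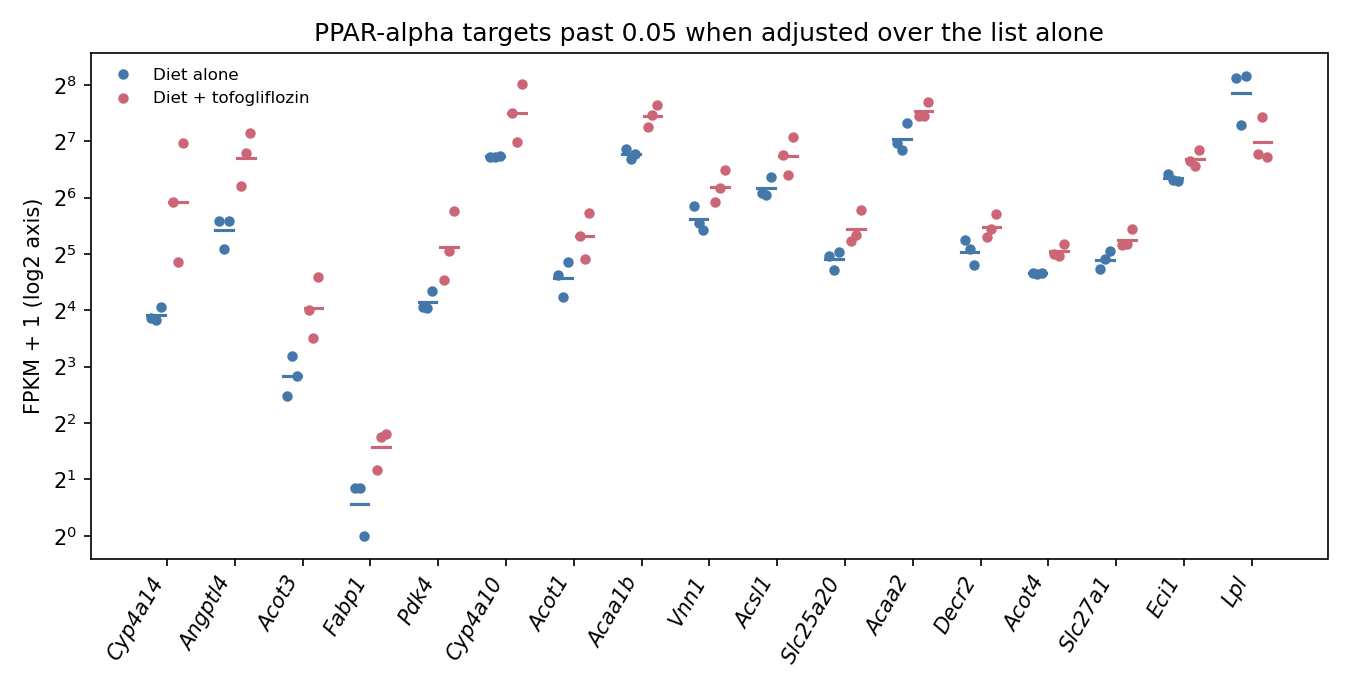
FPKM + 1 on a log2 axis of PPARα target genes among those that passed when adjusted over the list alone, 1 point per library, with a line at the mean of the log2 values of the 3 libraries of each group (blue, diet alone; red, diet with tofogliflozin). Of the genes shown, only Lpl lies lower with the drug; Cyp4a14 reaches 125 FPKM in tofogliflozin replicate 3.

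Of 30 genes of mitochondrial fatty acid oxidation, 22 had a change above 0 (median 0.10; camera adjusted p = 0.0308), and the adjusted p was 0.911 with an estimated correlation. None passed over the list alone (8 at an unadjusted limma p under 0.05). With a library left out, 1 fell without diet replicate 2, 1 rose without diet replicate 3, and 2 rose and 1 fell without tofogliflozin replicate 2. Eci1, an enoyl-CoA isomerase, was at 80.3 ± 3.73 and 103 ± 10.9 FPKM and Acsl1, an acyl-CoA synthetase, at 71.0 ± 9.01 and 108 ± 25.5 FPKM. Eci1, Acsl1 and many other genes of this list are also on the PPARα target list, so its camera call is not independent of that one. The camera call of this list also ended without diet replicate 2 (adjusted p = 0.649), tofogliflozin replicate 2 (0.0877) or tofogliflozin replicate 3 (0.197). Cpt1a, the entry enzyme of mitochondrial oxidation, was at 165 ± 11.6 and 189 ± 20.1 FPKM (limma adjusted p = 0.449), and Ppargc1a, a coactivator of oxidative metabolism, at 14.4 ± 2.82 and 16.6 ± 1.76 FPKM (0.573). Of 25 genes of peroxisomal fatty acid oxidation 4 rose and 4 fell over the list alone (camera adjusted p = 0.694, and 0.0453 without tofogliflozin replicate 1). Hacl1, of alpha-oxidation, rose from 22.0 ± 2.37 to 42.5 ± 12.3 FPKM and Pecr, a peroxisomal enoyl-CoA reductase, fell from 441 ± 32.9 to 324 ± 40.9 FPKM. In this list 4 rose and 0 fell without diet replicate 1, and 3 rose and 0 fell without tofogliflozin replicate 3. Without tofogliflozin replicate 1, 6 rose and 2 fell. These tests have fewer libraries, so a lost call does not show that the fall rested on the library left out.

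None of 27 genes of fatty acid and triglyceride synthesis passed over the list alone, 12 having a change above 0 (camera adjusted p = 0.861; 4 at an unadjusted limma p under 0.05). Without diet replicate 2 there were 2 and without diet replicate 3 there was 1. The median was -0.02 and the mean 0.03, so they differ in sign. Fasn was at 8.29 ± 0.724 and 7.19 ± 0.880 FPKM and Srebf1 at 14.5 ± 1.45 and 14.1 ± 0.917 FPKM (limma adjusted p = 0.509 and 0.908). Of 27 cholesterol synthesis genes 18 had a change above 0 (camera adjusted p = 0.405). When adjusted over the list alone 1 rose and 1 fell, and 1 in all passed without diet replicate 1, diet replicate 2, tofogliflozin replicate 1 or tofogliflozin replicate 3. Apoe was the 1 gene of 16 in cholesterol efflux to pass over the list alone, and rose from 181 ± 39.1 to 386 ± 85.3 FPKM. Without tofogliflozin replicate 1 or 3 no gene of this list passed (0 each). The efflux list had a median of -0.01 and a mean of 0.06 (camera adjusted p = 0.854), and Abca1 a log2 change of 0.22 (limma adjusted p = 0.547).

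Of 24 genes of lipid uptake and droplets none passed over that list alone (camera adjusted p = 0.803; 5 at an unadjusted limma p under 0.05), but 3 did without diet replicate 2 and 2 without tofogliflozin replicate 2. The fatty acid translocase gene Cd36 was at 169.9 ± 22.5 and 114 ± 17.6 FPKM, a log2 change of -0.57 (95% interval -0.87 to -0.27; limma adjusted p = 0.131 over all genes). Lpl, lipoprotein lipase, fell from 239 ± 73.3 to 128 ± 38.0 FPKM adjusted over the PPARα list alone. Its libraries overlapped (limma adjusted p = 0.225 over all genes). Plin2, a lipid droplet coat gene, was at 56.1 ± 2.14 and 62.4 ± 9.73 FPKM (limma adjusted p = 0.655). In the ketone body list of 10 genes 2 rose over the list alone (camera adjusted p = 0.784), among them Slc5a12, a lactate transporter gene, from 118 ± 8.58 to 161 ± 25.4 FPKM. The count was 0 without diet replicate 1 or tofogliflozin replicate 1, and 1 rose without tofogliflozin replicate 3. Without diet replicate 2, 3 rose and 2 fell, and 4 of the 10 had a change above 0.

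The title also names inflammation. Macrophage marker genes were lower as a group at camera's preset correlation (adjusted p = 0.000196), a call that was lost with an estimated correlation (adjusted p = 0.852) and without diet replicate 2 (0.548). Of these genes, 24 of 25 measured had a change below 0, with a median of -0.43. None passed either over all genes or over the list alone (limma; 2 at an unadjusted p under 0.05). Csf1r, the receptor for colony-stimulating factor, was at 18.4 ± 1.5 and 13.4 ± 2.24 FPKM and Lyz2, a lysozyme gene, at 44.9 ± 38.5 and 13.9 ± 4.52 FPKM. Cd68 was at 4.6 ± 1.93 and 2.81 ± 0.876 FPKM and Adgre1 at 4.06 ± 2.66 and 2.13 ± 0.751 FPKM. The diet libraries were far apart, with mean deviations of 0.04, 0.91 and -0.30 on the log2 scale against -0.18, -0.05 and -0.42 with tofogliflozin, so diet replicate 3 lay below all tofogliflozin libraries except replicate 3. Over the list alone 2 macrophage markers fell without diet replicate 3 and 1 without tofogliflozin replicate 2.

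Of 26 inflammatory cytokine and NF-κB target genes, 20 had a change below 0 (camera adjusted p = 0.00988; adjusted p = 0.702 with an estimated correlation). Over the list alone 3 fell and 1 rose. Il34, a cytokine that binds the Csf1r receptor, fell from 25.3 ± 9.91 to 7.90 ± 2.45 FPKM. Icam1, an adhesion molecule, fell from 11 ± 0.744 to 8.29 ± 0.754 FPKM and Myd88, an adaptor of Toll-like receptors, from 11.2 ± 1.39 to 8.54 ± 0.131 FPKM, and Nfkbia, the NF-κB inhibitor, rose from 29.7 ± 6.25 to 43.9 ± 5.26 FPKM. The camera call ended without diet replicate 2 (adjusted p = 0.446) or tofogliflozin replicate 3 (0.144). The 4 genes became 1 without diet replicate 1, 7 without diet replicate 3, 1 without tofogliflozin replicate 2, and 0 without tofogliflozin replicate 1 or 3. Il1b was at 2.27 ± 1.09 and 1.33 ± 0.673 FPKM and Lcn2 at 1.72 ± 1.78 and 2.22 ± 0.435 FPKM (limma adjusted p = 0.515 and 0.688). Ccl2 and Tnf stayed under the filter on low values. Ccl2 was at 0.776, 0.967 and 0.356 FPKM in the diet libraries and at 0.600, 1.53 and 0.172 FPKM with tofogliflozin. Tnf was at 0.167, 0.644 and 0.230 FPKM against 0.125, 0.0824 and 0 FPKM. Pparg, the adipogenic relative of Ppara, was also under the filter, at 0.851 ± 0.147 and 0.914 ± 0.128 FPKM.

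Among the other immune lists, 31 of 33 interferon response genes had a change below 0 (median -0.18), none of them passing over the list alone (limma; 0 at an unadjusted p under 0.05). Without diet replicate 3, in which these genes were low, 21 fell. Psmb9, an immunoproteasome subunit gene, was at 33.1 ± 23.0 and 14.5 ± 2.35 FPKM. Camera gave an adjusted p = 0.00527, and an adjusted p = 0.911 with an estimated correlation. The call ended without tofogliflozin replicate 3 (adjusted p = 0.0730), and also without diet replicate 2 (0.988, median -0.04, 15 of 33 above 0). Of 12 genes of MHC class II antigen presentation 10 had a change below 0 (camera adjusted p = 0.179). Cd74, the invariant chain gene, was at 3090, 3838 and 541 FPKM in the diet libraries and at 1128, 1447 and 740 FPKM with tofogliflozin. None passed over the list alone (limma; 0 at an unadjusted p under 0.05), and 9 fell without diet replicate 3, where camera called the list lower (adjusted p = 4.13e-10). In the complement list of 16 genes C3, the central component, rose from 4.66 ± 1.95 to 10.4 ± 2.02 FPKM and Cfi and Cd59a rose too, over the list alone (camera adjusted p = 0.929 for the list). Their count of 3 was 0 without diet replicate 1 or tofogliflozin replicate 3, 1 without diet replicate 2 or tofogliflozin replicate 1, and 8, with 5 of them lower, without diet replicate 3. Lymphocyte and neutrophil markers had 4 and 2 genes above the filter, too few for camera. Ccl5 was at 9.60 ± 5.35 and 7.35 ± 3.07 FPKM, and S100a9 rose from 3.64 ± 1.28 to 6.20 ± 1.13 FPKM over its 2 genes alone (limma adjusted p = 0.223 over all genes). This did not hold without diet replicate 1, diet replicate 2 or tofogliflozin replicate 3 (0 genes each), and 2 genes passed without diet replicate 3. No lymphocyte marker passed over the list alone (limma; 0 at an unadjusted p under 0.05), and 1 fell without diet replicate 3.

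No gene of 31 in the extracellular matrix list passed over the list alone (limma; 2 at an unadjusted p under 0.05; 1 passed without tofogliflozin replicate 3; camera adjusted p = 0.694). Col1a1 and Tgfb1 had log2 changes of -0.28 and -0.45 (limma adjusted p = 0.700 and 0.428). Camera called this list lower without tofogliflozin replicate 1 (adjusted p = 0.0112) and higher without tofogliflozin replicate 3 (0.0347), so it turned direction. Timp3, a metalloproteinase inhibitor, was at 503 ± 48.6 and 382 ± 31.5 FPKM. Tubular injury markers moved both ways. Over the list alone Cp, ceruloplasmin, rose from 11.3 ± 1.72 to 18.5 ± 0.892 FPKM and Anxa2, an annexin, from 31.4 ± 0.315 to 37.3 ± 1.41 FPKM. Itgb6, an integrin of injured epithelium, fell from 15.3 ± 5.60 to 7.03 ± 0.957 FPKM and Gdf15, a stress-induced cytokine, from 16.3 ± 6.51 to 6.64 ± 2.55 FPKM. Of 23 measured, 18 had a change above 0 (camera adjusted p = 0.0482; adjusted p = 0.659 with an estimated correlation), and the call ended without diet replicate 1 (0.149), diet replicate 3 (0.20), tofogliflozin replicate 1 (0.0920) or tofogliflozin replicate 3 (0.0800). The 4 injury genes became 2 without diet replicate 1, 1 without tofogliflozin replicate 1 and 2 without tofogliflozin replicate 3. Havcr1, the gene of kidney injury molecule KIM-1, was under the filter at 0.422, 0.0701 and 0.0646 FPKM in the diet libraries and 0.979, 1.39 and 0.187 FPKM with tofogliflozin.

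**Figure D3:**
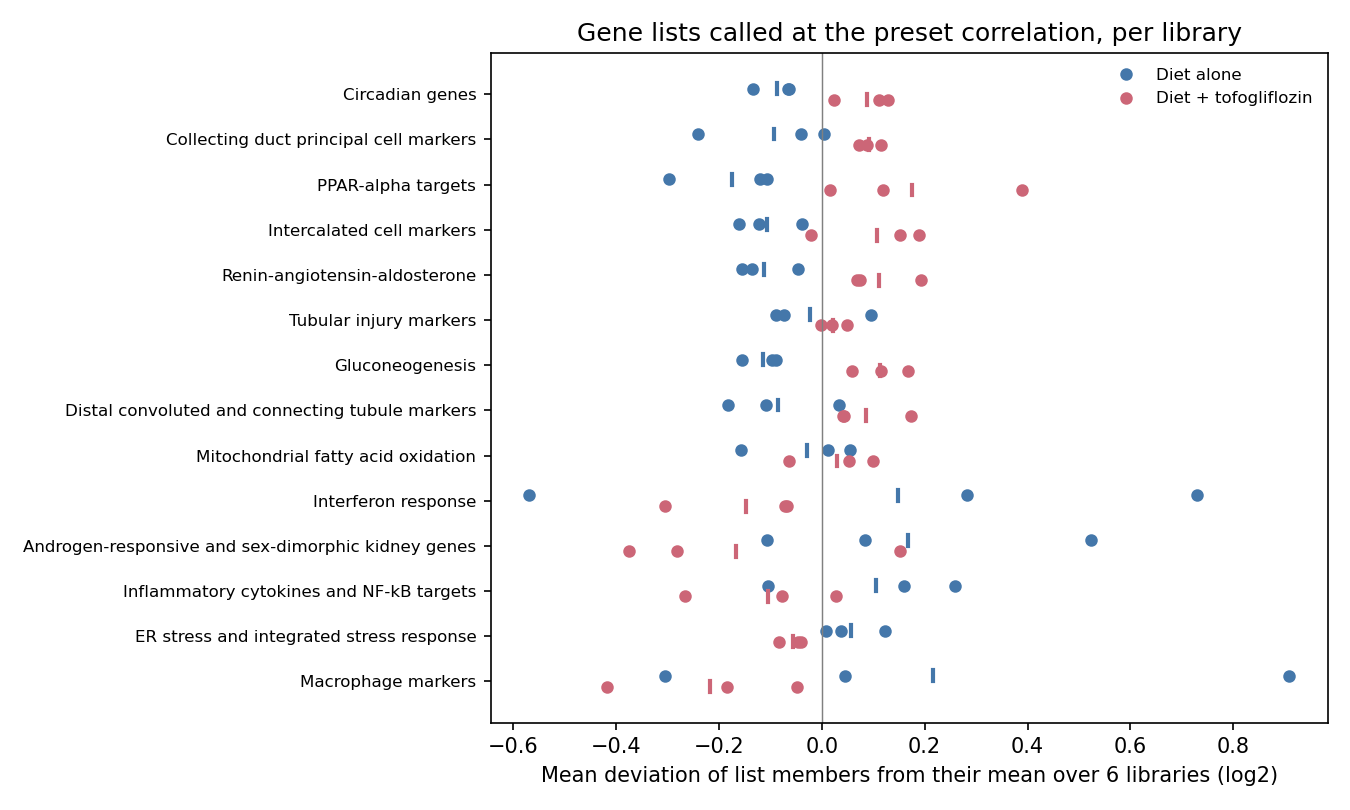
Mean deviation of the members of each list from their mean over the 6 libraries, on the log2 scale, for the 14 lists called at camera's preset correlation; each point is a library (blue, diet alone; red, diet with tofogliflozin) and each short line a group mean. The macrophage markers reach 0.91 in diet replicate 2 and lie at -0.30 in diet replicate 3, and the PPARα targets reach 0.39 in tofogliflozin replicate 3.

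Glucose handling was examined because tofogliflozin blocks renal glucose reabsorption. Of 17 gluconeogenesis genes 15 had a change above 0, with a median of 0.16 (camera adjusted p = 0.000196; adjusted p = 0.444 with an estimated correlation). Pck1, phosphoenolpyruvate carboxykinase, rose from 1784 ± 252 to 3153 ± 874 FPKM (limma adjusted p = 0.181 over all genes). G6pc, glucose-6-phosphatase, rose from 239 ± 47.5 to 402 ± 32.4 FPKM. In all, 3 genes rose over the list alone, these among them. Without diet replicate 2, 7 genes rose over the list alone. Slc5a2 was at 181 ± 36.3 and 164 ± 3.68 FPKM (limma adjusted p = 0.746, 95% interval of the log2 change -0.43 to 0.18). Slc5a1, which encodes SGLT1, was at 17.2 ± 3.41 and 17.0 ± 0.883 FPKM (0.997), and Slc2a2, which encodes the glucose transporter GLUT2, at 78.6 ± 5.41 and 82.8 ± 5.08 FPKM (0.746). No gene of 16 in glycolysis or of 45 in oxidative phosphorylation passed over its list alone (camera adjusted p = 0.502 and 0.386; 0 at an unadjusted limma p under 0.05 in each). Oxidative phosphorylation was called higher by camera without diet replicate 3 (adjusted p = 0.00390, 37 of 45 above 0). Without diet replicate 2 the change was above 0 in 14 of its 45 genes, with a median of -0.04.

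In the renin-angiotensin-aldosterone list of 12 genes, 5 rose and 1 fell over the list alone. Sgk1, a kinase induced by aldosterone and glucocorticoids, rose from 28.7 ± 6.87 to 66.1 ± 10.3 FPKM. Scnn1a, a subunit of the epithelial sodium channel, rose from 45.9 ± 2.14 to 61.3 ± 4.23 FPKM. Ace, which encodes angiotensin-converting enzyme, fell over the list alone from 58.8 ± 11.3 to 38.5 ± 8.82 FPKM, with overlapping libraries (limma adjusted p = 0.214 over all genes). Camera gave an adjusted p = 0.00154, and an adjusted p = 0.659 with an estimated correlation. Over the list alone 3 genes passed without diet replicate 1, tofogliflozin replicate 1 or tofogliflozin replicate 3. Of 22 genes of endoplasmic reticulum stress and the integrated stress response, 10 fell and 2 rose over the list alone (camera adjusted p = 0.00747; adjusted p = 0.659 with an estimated correlation). The chaperone gene Hspa5 fell from 316 ± 11.8 to 250.2 ± 26.4 FPKM, Hyou1 from 43.0 ± 2.95 to 33.1 ± 2.27 FPKM and Manf from 34.6 ± 0.886 to 27.8 ± 2.34 FPKM. Herpud1, of the degradation pathway, rose from 247 ± 26.1 to 334 ± 38.6 FPKM. No gene of the stress list passed over the list alone without diet replicate 1, tofogliflozin replicate 2 or tofogliflozin replicate 3 (0 each), and 7 did without diet replicate 3.

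Of 29 genes of oxidative stress and NRF2 targets, 3 rose and 1 fell over the list alone (camera adjusted p = 0.203). Camera called this list lower without diet replicate 3 (adjusted p = 0.0107) or tofogliflozin replicate 2 (0.00915). Nox4, a hydrogen peroxide-producing oxidase, rose from 108 ± 7.63 to 157 ± 12.9 FPKM and Gsta2, a glutathione transferase, from 184 ± 68.8 to 394 ± 45.4 FPKM. Gclm, of glutathione synthesis, fell from 124 ± 9.02 to 92.0 ± 10.6 FPKM. Without diet replicate 1 the 4 genes became 1, without tofogliflozin replicate 1 they became 2 and without tofogliflozin replicate 3 they became 0. Among 14 genes of bile acid transport, Abcb1b, an efflux pump, rose from 3.14 ± 0.631 to 6.47 ± 1.81 FPKM. The transporter genes Slco1a1 and Slc51a fell, from 125 ± 48.4 to 57.9 ± 20.3 FPKM and from 94.7 ± 12.2 to 61.8 ± 18.4 FPKM, over the list alone (camera adjusted p = 0.386). The libraries of Slc51a overlapped (limma adjusted p = 0.216 over all genes). The 3 genes of this list became 5 without diet replicate 2 and 0 without diet replicate 1, diet replicate 3, tofogliflozin replicate 1 or tofogliflozin replicate 3.

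Markers of the distal nephron were higher as groups. All 15 intercalated cell markers had a change above 0 and 4 rose over the list alone (camera adjusted p = 5.50e-05; adjusted p = 0.659 with an estimated correlation). Rhcg, an ammonia transporter, rose from 63.1 ± 4.05 to 77.2 ± 4.56 FPKM and Atp6v1c2, a proton pump subunit, from 16.3 ± 1.31 to 21.5 ± 1.30 FPKM. None passed without diet replicate 1, tofogliflozin replicate 1 or tofogliflozin replicate 3 (0 each). Of 12 collecting duct principal cell markers 4 rose over the list alone (camera adjusted p = 0.00747, but 0.659 with an estimated correlation and 0.0793 without diet replicate 1). Without diet replicate 2, 6 of them rose and 1 fell. The sodium channel subunit Scnn1g rose from 13 ± 0.388 to 17.7 ± 0.179 FPKM and the water channel Aqp4 from 6.94 ± 1.84 to 12.5 ± 1.86 FPKM. All 14 markers of the distal convoluted and connecting tubule had a change above 0 and none passed over the list alone (limma; 3 at an unadjusted p under 0.05; 2 passed without diet replicate 3). Calb1, a calcium-binding protein, was at 86.4 ± 15.5 and 111 ± 2.85 FPKM (camera adjusted p = 0.00474; adjusted p = 0.659 with an estimated correlation; 0.0587 without tofogliflozin replicate 3).

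Proximal tubule S1 and S2 markers went both ways, 3 up and 3 down over the list alone of 24, with a median of -0.0030 and a camera adjusted p = 0.784. Of these markers 2 passed without diet replicate 1 and 0 without tofogliflozin replicate 1 or 3. Slc22a8, an organic anion transporter, rose from 169.6 ± 26.8 to 254 ± 16.8 FPKM, and Slc22a12, a urate transporter, fell from 1122 ± 224 to 688 ± 107 FPKM. Of 16 S3 segment markers 3 rose, Bcat1 among them, and 5 fell over the list alone (camera adjusted p = 0.356). In all, 3 passed without diet replicate 1 and 2 without diet replicate 3, tofogliflozin replicate 1 or tofogliflozin replicate 3. Atp11a, a phospholipid flippase, fell from 371 ± 33.9 to 252 ± 18.2 FPKM.

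Podocyte (adjusted p = 0.116), loop of Henle (0.784), endothelial (0.784), medullary osmolyte (0.488), adipocyte (0.334) and red blood cell markers (0.784) were not called by camera. Over the list alone no podocyte, loop of Henle, endothelial, red blood cell, urothelial or adrenal marker passed (limma; 4, 3, 0, 0, 1 and 0 at an unadjusted p under 0.05). Without diet replicate 3, 2 red blood cell markers passed. Aqp4 was the 1 medullary gene to pass over that list alone, and none did without tofogliflozin replicate 1 or 3. Podxl, of the podocyte surface, was at 44.2 ± 1.43 and 49.6 ± 2.22 FPKM. Cldn10, a claudin of the loop of Henle, was at 216 ± 1.78 and 179 ± 12.9 FPKM, and Cdh5, of endothelial junctions, at 9.0 ± 0.501 and 7.84 ± 0.459 FPKM. Car3, a carbonic anhydrase on the adipocyte list, rose over all genes from 29.2 ± 4.19 to 50.8 ± 2.94 FPKM (limma adjusted p = 0.0391), and Lpl fell over the adipocyte list alone. In the adipocyte list 1 rose and 0 fell without diet replicate 1, diet replicate 3 or tofogliflozin replicate 3. Without tofogliflozin replicate 1, 2 rose and 0 fell, so Lpl did not pass there either. Hbb-b1, a haemoglobin gene, was at 5.18, 0.730 and 55.4 FPKM in the diet libraries and 25.1, 41.5 and 9.94 FPKM with tofogliflozin. Urothelial and adrenal markers had 4 and 2 genes above the filter, too few for camera, and Psca and Akr1b7 had log2 changes of -0.52 and -0.18 (limma adjusted p = 0.337 and 0.725).

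Of 20 circadian genes, 7 rose and 3 fell over the list alone (median 0.27; camera adjusted p = 0.00543; adjusted p = 0.444 with an estimated correlation). Cry2, a repressor of the clock, rose from 7.31 ± 0.423 to 10.04 ± 0.707 FPKM and Usp2, a clock-controlled deubiquitinase, from 57.9 ± 7.52 to 80.1 ± 9.78 FPKM. The activators Arntl and Npas2 fell, from 2.49 ± 0.444 to 1.22 ± 0.529 FPKM and from 1.68 ± 0.488 to 0.627 ± 0.327 FPKM. Nr1d1, another clock gene, named outside the rule, also fell (log2 change -0.45, limma adjusted p = 0.267 over all genes). Over the list alone 1 passed without diet replicate 1, 2 without diet replicate 3 and 0 without tofogliflozin replicate 2 or 3. The hour at which the tissue was taken is not in the labels.

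Of 14 androgen-responsive and sex-dimorphic kidney genes, 7 fell and 1 rose over the list alone (median -0.20, camera adjusted p = 0.00747, but 0.772 with an estimated correlation). Kap, on this list but named outside the rule, overlapped between the groups. It was at 62009.5, 45152.4 and 63006.3 FPKM in the diet libraries and at 61595.8, 70175.8 and 56824.8 FPKM with tofogliflozin. Odc1, ornithine decarboxylase, fell from 766 ± 272 to 345 ± 133 FPKM and Cndp2, a dipeptidase, from 888 ± 229 to 418 ± 54.2 FPKM, while Gsta4, a glutathione transferase, rose from 21.4 ± 4.48 to 31.0 ± 2.30 FPKM. The camera call ended without diet replicate 1 (adjusted p = 0.0708) or tofogliflozin replicate 3 (0.0524), and 4 genes passed over the list alone without diet replicate 1 and 1 without tofogliflozin replicate 1 or 3.

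Of 20 immediate early genes, Klf2, a flow-responsive factor, rose from 8.64 ± 2.02 to 13.4 ± 1.69 FPKM. Cyr61 and Junb fell, from 22.3 ± 2.49 to 15.1 ± 3.36 FPKM and from 20.1 ± 2.42 to 12.4 ± 3.64 FPKM, over the list alone (camera adjusted p = 0.784). The 3 genes became 1 without diet replicate 1 or tofogliflozin replicate 1 and 0 without diet replicate 2, diet replicate 3 or tofogliflozin replicate 3. None of 14 cell cycle genes passed over the list alone (limma; 1 at an unadjusted p under 0.05; camera adjusted p = 0.116). Camera called this list lower without diet replicate 1 (adjusted p = 0.0324), diet replicate 3 (0.0273) or tofogliflozin replicate 1 (0.00430). Mcm6, a replication helicase subunit, was at 7.53 ± 0.462 and 6.36 ± 1.01 FPKM.

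In all, camera called 14 of 37 lists at its preset correlation, 9 higher and 5 lower. Some lists share many genes, so these calls are not independent. With an estimated correlation camera called none, the smallest adjusted p being 0.444, and 2 lists had an unadjusted p under 0.05. Fry, which asks whether the genes of a list move on balance one way, called none either (8 at an unadjusted p under 0.05), and its mixed version, which asks whether they change in either direction, called 13.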

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

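Leave-out counts over single lists were chosen after the data were seen; all other settings were planned. Against 31 changed genes, the count was 1 with no filter on low values, 20 at 5 FPKM and 47 with upper-quartile scaling. It was 123 with array weights, 61 with a robust trend and 152 at a threshold of 0.1, and 2 to 66 when a library was left out. The 31 were all among the 47 and the 123. They are among the 152 by construction, since only the threshold differs. The cause of these differences in count was not tested, except that more genes were tested without a filter (17726) and fewer at 5 FPKM (8754). Pseudocount 0.1, quantile normalization and no trend gave 21, 28 and 25. Bcat1 passed throughout (adjusted p 0.000133 to 0.0119), and the other named genes that passed kept their direction, with 4 (Chst11) to 14 (Hyal1) of their settings past the threshold. No call of a single gene reversed; over all named genes, 109 pairs of gene and setting lost a call and 51 gained one.

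Against 14 called lists, 0 were called with an estimated correlation, 0 by fry, and 9 to 17 with a library left out, the 9 without tofogliflozin replicate 3. The adjusted p with an estimated correlation and by fry was 0.659 and 0.323 for PPARα targets, 0.911 and 0.756 for mitochondrial fatty acid oxidation, 0.702 and 0.391 for inflammatory genes, 0.852 and 0.756 for macrophage markers, and 0.659 and 0.291 for tubular injury markers. Mitochondrial fatty acid oxidation was also lost with quantile normalization (0.0519) and array weights (0.289), inflammatory genes at 5 FPKM (0.0515), and tubular injury markers with upper-quartile scaling (0.0524), quantile normalization (0.0519) and no trend (0.0621). With a library left out, adjusted p ran from 4.45e-15 to 0.000281 for PPARα targets, which kept their call, 0.00138 to 0.649 for mitochondrial fatty acid oxidation, 0.000395 to 0.446 for inflammatory genes, 6.33e-11 to 0.548 for macrophage markers, 0.0112 to 0.988 for the extracellular matrix list and 0.0102 to 0.20 for tubular injury markers. The extracellular matrix list, not called with all libraries, was called lower without tofogliflozin replicate 1 (0.0112) and higher without tofogliflozin replicate 3 (0.0347). Other lists not called with all libraries gained a call: lymphocyte markers (0.0298; too few for a test with the filter) and cell cycle (0.00319) with no filter, cell cycle also without diet replicate 1 (0.0324), diet replicate 3 (0.0273) or tofogliflozin replicate 1 (0.00430), MHC class II (4.13e-10) and oxidative phosphorylation (0.00390) without diet replicate 3, NRF2 targets without diet replicate 3 (0.0107) or tofogliflozin replicate 2 (0.00915), and peroxisomal oxidation without tofogliflozin replicate 1 (0.0453). The interferon call ended without diet replicate 2 (0.988; 4.76e-18 to 0.988 over its alternatives), where the median of its members was -0.04. Lists and genes uncalled in both settings changed sign in 30 and 26 pairs. The list tests were not run with a robust trend or at a threshold of 0.1. The cause was not tested.

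With the replicate number as a block, 26 genes were called, 18 of them shared with the 31, and 14 lists; tubular injury markers were lost (0.0988) and MHC class II was gained (0.0119). A call lost with the block is not read as a weaker effect. The deviations of same-numbered libraries correlated at -0.0549, -0.0623 and 0.0514. Replicate numbers 1 and 2 correlated best with another number, and 3 with its own. No clear pairing by number was seen, but 3 such correlations are too few to exclude a batch shared by number. Upper-quartile scaling and quantile normalization shifted the median of all genes by 0.0049 and 0.0026 (log2). Depth limits genes near 1 FPKM, where 15.7 to 20.3 fragments lie behind a 2 kb transcript.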

Other observations

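The tests of explanations in this part were chosen only after the results were seen. The exception is the glucocorticoid-responsive list, which was written with its prediction before the values of its members were seen. The camera results quoted for the other lists, also with a library left out, were planned. All bootstrap intervals in this part resample genes, so they do not measure the spread between mice.

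PPARα targets were higher at the preset correlation and not called with an estimated correlation (adjusted p = 0.659; 4.45e-15 to 0.659 over the alternatives). The S1 and S2 markers of the proximal tubule had a median of -0.0030 (95% bootstrap interval over genes -0.12 to 0.07), against 0.19 for the targets. With a library left out the median of the targets ran from 0.11 to 0.28. These values argue against a rise of proximal tubule RNA as large as that of the targets. The markers went both ways, 12 above and 12 below 0, so a smaller rise in its share cannot be excluded. The phase score is the mean of clock genes of the Dbp phase minus that of clock genes of the Arntl phase. Of the Dbp-phase genes, Nr1d1 fell (log2 change -0.45) and all others had a change above 0. A shift of clock phase stays open: the mean phase scores of the groups differed by 0.92 (nearest libraries -0.21 and 0.13), so phase and drug cannot be told apart between groups. Within groups the correlation of phase and PPARα scores was 0.176 over 6 libraries. The minus log10 p of the list was 10.15 in the real split and at most 13.98 in the other splits, with 3 of 10 splits as high, and 10 splits are too few for a share under 0.05. An effect of the drug, which the design names, may explain the difference and stays open beside clock phase and a smaller rise in proximal tubule share, untested.

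Macrophage and interferon genes were lower as groups at the preset correlation and not called with an estimated correlation (adjusted p = 0.852 and 0.911). A lower share of all non-tubule cells is argued against by the endothelial and podocyte markers, whose median lay 0.46 above that of the macrophage markers (95% bootstrap interval over genes 0.36 to 0.56), and by 0.11 (0.02 to 0.25) without diet replicate 2, on which most of the gap rested. A high level in only part of the diet libraries was not tested independently: that the lowest diet library lay below the highest tofogliflozin library (-0.26) is the observation that raised it. Without diet replicate 2 the macrophage call ended (adjusted p = 0.548; 6.33e-11 to 0.852 over the alternatives) and so did that of the interferon list (0.988; 4.76e-18 to 0.988). Both this explanation and an effect of the drug stay open.

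Androgen-responsive and sex-dimorphic genes were lower as a group at the preset correlation and not called with an estimated correlation (camera adjusted p = 0.772), and Kap overlapped between the groups. Animals of different sex are argued against by Xist, at most 0.0388 FPKM, and Ddx3y, at least 9.87 FPKM, in all 6 libraries. A smaller share of S3 segment RNA cannot be told apart, since the S3 markers outside the list had a median of -0.042 with a 95% bootstrap interval of -0.34 to 0.0007, which holds the -0.20 of the androgen list. An effect of the drug stays open, and the call ended without diet replicate 1 (adjusted p = 0.0708) or tofogliflozin replicate 3 (0.0524; 0.00128 to 0.772 over the alternatives).

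Tsc22d3 and Sgk1 are induced by glucocorticoids, as is the clock gene Per1, singled out after its values were seen (log2 change 0.93, adjusted p = 0.229), so a list of 18 other glucocorticoid-responsive genes was tested. Of 16 measured, 14 had a change above 0 (median 0.49, 95% bootstrap interval 0.18 to 0.73), and camera, run on this list alone without adjustment, gave a p of 2.14e-06, which was 0.0805 with an estimated correlation. Among them were Zbtb16 (1.18), Map3k6 (0.86) and Mt1 (0.58), chosen after their values were seen. The p was 0.00306 without diet replicate 2, where 10 of the genes were above 0. With another single library left out, p ran from 1.26e-09 to 0.000118. No member passed over all genes (limma; 7 higher and 1 lower at an unadjusted p under 0.05), and 3 of the genes are also in other lists. A glucocorticoid-type response, to the drug or to handling, is a candidate explanation that the design cannot separate from the groups. Clock phase stays open here too. Its scores were apart between the groups (nearest libraries -0.21 and 0.13), and the hour of sampling is not in the labels.

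The real split gave 31 changed genes and no other split of the 6 libraries more than 2, so 1 of 10 splits gave as many. For called lists the real split gave 14 and the highest other 16, with 3 of 10 splits giving as many or more. In both cases 10 splits are too few for a share under 0.05.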
